A study of Homo sapiens with 13 samples.

How the data were processed

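Gene expression was measured by bulk RNA sequencing in 13 libraries from human H9 embryonic stem cells that carry a doxycycline-inducible NEUROG2 gene. The libraries fall into 9 groups. A first set of 5 libraries, 1 per group, holds cells at day 0 and cells grown for 5 or 11 days with or without doxycycline. A second set of 8 libraries holds 4 groups of 2, in which every culture received doxycycline for 6 days and differed in FGF2 and in the day of harvest. The titles name the libraries of a group hES-N2G1 and hES-N2G2, taken here as replicates 1 and 2, while the source names give hES-N1 for all 13 libraries. Whether the numbers mark cultures, clones or lines is not stated. The sets were sequenced in separate runs, and no value was compared between them without saying so. The descriptions of both day-12 controls give 6 days of growth, but their titles give day 12 and the periods listed add up to 12 days, so they were taken as day 12. Late FGF2 is labelled as days 6 to 12 in 1 field and as days 7 to 12 in another. Per the labels, doxycycline was given at 1 µg/ml and FGF2 at 20 µg/ml.

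The authors deposited a table of raw read counts per gene for each set. Reads were counted with Subread and featureCounts 1.5.0 on GRCh38, per the submitters' processing notes. The aligner settings and the GENCODE release were not stated. The doxycycline table has 60500 genes, of which 41723 had counts, and includes the reporters EGFP and mCherry. The FGF2 table has 60554 genes, of which 38116 had counts. The authors also deposited normalized signal values for the doxycycline set, made with limma voom per the file name, on a linear scale and for 26282 genes. They were used here only as an alternative to the counts. For the FGF2 set the authors deposited tables of log2 fold changes with p-values from DESeq2 and limma, for early and for late FGF2. Versions and models of these were not stated. The 16 per-sample columns inside those 4 tables repeat the counts and were not used here.

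Genes were named by the symbol in the deposited tables where one was given (26349 identifiers) and otherwise by the reference annotation (30921 identifiers). The remaining 3369 identifiers kept their identifier as a name. Coordinates, gene lengths, GC content and the share of a gene's exon bases that another gene overlaps were taken from the GRCh38 reference annotation.

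The 8 FGF2 libraries were fitted together with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups, which left 20142 genes. Library sizes were scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted, and each comparison was a two-sided test with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. The comparisons were early FGF2 against its control on day 6, late FGF2 against its control on day 12, the difference between these effects, and the day-12 control against the day-6 control. Levels are TMM-scaled CPM, counts scaled to 1e6 reads, given as mean ± SD with n = 2.

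The 5 doxycycline libraries have no replicates, so no test was run on them. Their TMM-scaled CPM were compared as log2 ratios after adding 1 CPM to both values. Genes with at least 10 CPM in either library were counted as different when the ratio was at least 4-fold. Counting intervals of ratios are 95% exact binomial intervals. Totals were 28443657 to 47159475 counts in the doxycycline set and 22802501 to 30014661 in the FGF2 set. A count of 0 was compared through a floor of 3 counts, over the group in the FGF2 set. Intervals and floors cover counting error only.

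A total of 30 gene lists, for cell types, pathways and stress responses, were fixed before the data were examined. In the FGF2 set each list with at least 5 tested members was compared with all other genes by camera with a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it (limma 3.58.1). In the doxycycline set each list with at least 5 members at 1 CPM or more was described by its median log2 ratio. That median was ranked among 10000 random lists matched on expression in 20 bins. Genes at least 4-fold higher, or lower, with doxycycline on both days were also tested as sets in the FGF2 fit.

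The rule for named genes was also fixed before the data were examined. NEUROG2, NEUROD1, FGF2, its 4 main receptors and the reporters came first. Next came the 10 called genes with the largest rise and the 10 with the largest fall with late FGF2, and 6 each way for the difference and for day 12 against day 6. These had to have a gene symbol of a named gene, a mean of at least 5 CPM and the same direction in both numbered pairs of libraries. For lists, up to 4 called members of smallest p were named. In the doxycycline set the 10 highest and 10 lowest genes by the mean of both days were named, with up to 4 members of highest CPM per list. Not all genes that the rule gives are used here. Other genes were named after their values were seen, and the text says so.

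The procedures were tested on simulated data in which each gene varied independently, with counting error only in the doxycycline libraries. False list calls from genes that vary together were therefore not covered. For early FGF2 the fit recovered 2, 29, 37 and 44 of 50 genes changed 1.25-, 1.5-, 2- and 4-fold, and called 11 unchanged genes. For late FGF2 it recovered 4, 18, 33 and 45, and called 5 unchanged genes. For the difference it recovered 2, 11, 25 and 39, and called 8 unchanged genes. For day 12 against day 6 it recovered 2, 24, 37 and 44, and called 12 unchanged genes. Of 200 unshifted lists, 10, 5, 7 and 6 had a camera p under 0.05 in these comparisons, and a shifted list had a p of 1.2e-27 or less in each. In simulated doxycycline libraries none of 50 genes changed 2- or 3-fold passed the 4-fold threshold on either day. At 6-fold 48 passed on both days, and at 12-fold 48 passed on day 5 and 47 on day 11. The shifted list reached the percentile 100 on both days, and 3 and 0 of 40 unshifted lists fell outside the central 95%.

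Alternatives were DESeq2 1.42.0, limma voom, RLE size factors, library totals without scaling, no filter on low counts, a filter of 5 CPM in at least 2 libraries, a fit of only the 4 libraries compared, a 2-fold threshold, leaving out each library in turn, and the sample number as a block. For the doxycycline set they were pseudocounts of 0.25 and 5 CPM, library totals, a minimum of 1 CPM and a 2-fold threshold. A correction for gene length and GC content was added after the data were seen. It used regression splines with 5 degrees of freedom on genes with a mean log2 CPM of at least 2. The early lists without 1 day-6 library, and the authors' normalized values, were also added then. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.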

Results

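RNA was sequenced from H9 human embryonic stem cells that express NEUROG2, a proneural transcription factor, when doxycycline is given. The labels describe the product as post-mitotic excitatory neurons and ask how the growth factor FGF2 changes gene expression in them. All treated and untreated cultures spent 2 days in E8 stem cell medium and then changed to 3N, a neural medium. In the doxycycline set, 1 library was made from day 0 and 1 from each of day 5 and day 11 with and without doxycycline. These libraries held 28443657 to 47159475 counted reads, and none of them has a replicate. In the FGF2 set all cultures received doxycycline for 6 days. Early FGF2 was present on days 1 to 6 together with doxycycline, and the cells were harvested on day 6. Late FGF2 was added for 6 days after doxycycline was withdrawn, and the cells were harvested on day 12. Each of the 4 groups of this set had 2 libraries, with 22802501 to 30014661 reads, and a principal component of the day of harvest held 89.3% of the variance.

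Cultures with and without doxycycline differed in NEUROG2 and in doxycycline itself, and no library had doxycycline without the inducible gene. NEUROG2 (chromosome 4, 112513516 to 112516172, GRCh38) was at 1.34 CPM on day 5 without doxycycline and at 1564 CPM with it. On day 11 it was at 6.26 and 1018 CPM. The position is that of the cells' own gene. Here and below, the counts were not split between that gene and the inducible copy. The EGFP reporter was at 87.2 and 1290 CPM on day 5 and at 25.8 and 742 CPM on day 11, while the mCherry reporter was at or near 0 in all 5 libraries. STMN2, a microtubule regulator of growing axons, was at 2.00 CPM without and 4019 CPM with doxycycline on day 5, and at 9.76 and 3666 CPM on day 11. NEUROD1, a target of NEUROG2, was at 24.9 CPM with doxycycline on day 5 and at 0.848 CPM on day 11.

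Neuronal genes held the highest ratios on both days. Among the 10 genes with the highest ratios were the cytoskeletal genes STMN2, STMN4, DCX, NEFL and NEFM, the vesicle protein SYT4 and the transcription factors ONECUT3, EBF3 and NEUROG2, the induced gene itself. NEFL went from 10.5 to 2852 CPM with doxycycline on day 5 and from 14.1 to 5655 CPM on day 11. NEFM shares 38.9% of its exon bases with an antisense gene. The list of pan-neuronal genes had a median log2 ratio of 5.93 on day 5 and 5.87 on day 11, with 20 and 23 of its 25 members at least 4-fold higher. Sensory, peripheral and cholinergic genes had medians of 5.22 and 4.27, and ISL1 (0.343 to 420 CPM), P2RX3 (1.03 to 555 CPM) and RET (39.8 to 404 CPM) were examples on day 5. The glutamate transporter SLC17A6 was at 304 CPM with doxycycline on day 5, against 2 counts without it. Voltage-gated ion channel genes had medians of 1.57 and 3.02, and synaptic genes of 2.54 and 3.05. NEUROG2 downstream proneural genes had medians of 3.56 and 1.86, and NHLH1, one of them, was at 856 CPM on day 5 and at 78.0 CPM on day 11. Axon guidance genes had medians of 2.65 and 1.55, glutamatergic genes of 1.14 and 2.62, and cholesterol synthesis genes of 1.62 and 1.07. GABAergic genes had a median of -0.04 on day 5 and 1.61 on day 11, and midbrain and isthmus genes of 2.07 and -0.21. The midbrain and isthmus median of the day-11 control was itself 2.00 above day 0.

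**Figure D1:**
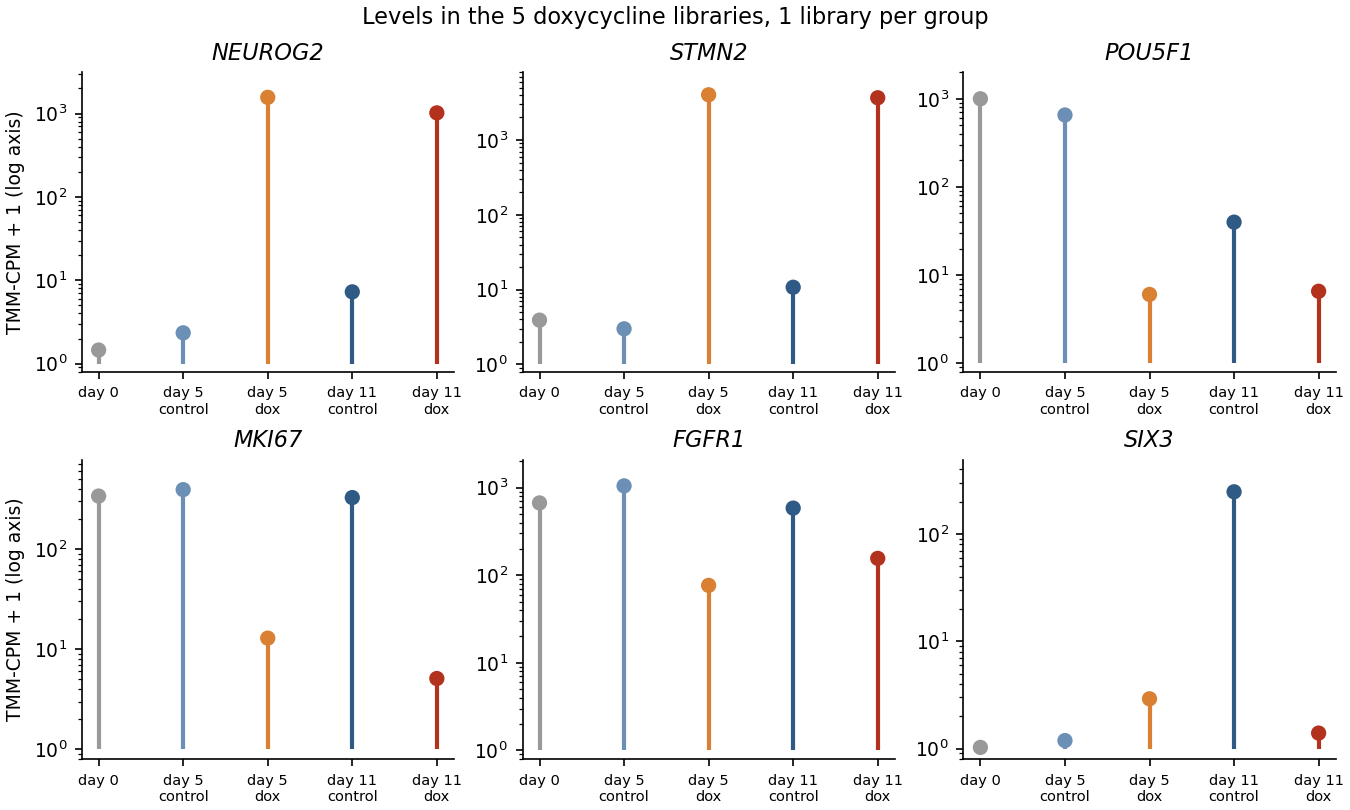
Levels of 6 genes in the 5 doxycycline libraries, 1 library per group, as TMM-scaled CPM plus 1 on a log axis. NEUROG2 and STMN2 were higher with doxycycline on both days, POU5F1, MKI67 and FGFR1 were lower, and SIX3 was at 246 CPM on day 11 without doxycycline.

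Stem cell, epithelial and cell cycle genes were lower with doxycycline. The pluripotency factor POU5F1 was at 654 CPM without and 5.03 CPM with doxycycline on day 5, and the epithelial cadherin CDH1 was at 341 and 1.28 CPM. MKI67, a marker of dividing cells, was at 392 and 11.9 CPM on day 5 and at 326 and 4.09 CPM on day 11. Epithelial genes had medians of -4.43 on day 5 and -4.55 on day 11, cell cycle genes of -3.82 and -4.54, pluripotency genes of -3.36 and -2.06, and mesenchyme and matrix genes of -2.55 and -2.43. Among the 10 genes with the lowest ratios were CDH1, SFRP2, COL4A6, COL2A1, ITGB5, MFGE8, ESRP1, FZD5 and COL4A5. Neural progenitor genes had medians of -0.45 and -4.09, and SOX2 was at 306 CPM without and 17.5 CPM with doxycycline on day 11. The 4 main FGF receptors were also lower on both days. On day 5 FGFR1 was at 1047 CPM without and 75.6 CPM with doxycycline, FGFR2 at 199 and 11.0 CPM, FGFR3 at 169 and 1.74 CPM and FGFR4 at 112 and 1.69 CPM. FGF2 messenger RNA was at 338 and 9.94 CPM on day 5. The FGF ligand and receptor list had medians of -1.17 and -1.10, and the list of FGF and ERK feedback targets of -0.88 and -0.72. DUSP4, a phosphatase of that list, went the other way, from 8.29 to 328 CPM on day 5. Further medians below the random lists on day 5 were those of mitochondrial messenger RNA (-1.91), astroglia and oligodendroglia (-1.63), p53 and apoptosis (-1.09), BMP and TGF-beta (-0.87), immediate early genes (-0.69), hypoxia and glycolysis (-0.55) and the stress response (-0.46). On day 11 these medians were 0.44, -0.36, -0.45, -2.77, -0.18, -1.44 and 0.59. Medians of -1.60 for Notch, -1.55 for WNT, -2.42 for neural crest and Schwann and -1.05 for mesendoderm genes lay below the random lists on day 11. On day 5 they were -0.17, -0.43, -0.71 and -0.0049. Cortical and forebrain genes lay within the random lists on both days, with 0.74 and -0.63, and too few HOX and caudal genes were measured for a median.

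**Figure D2:**
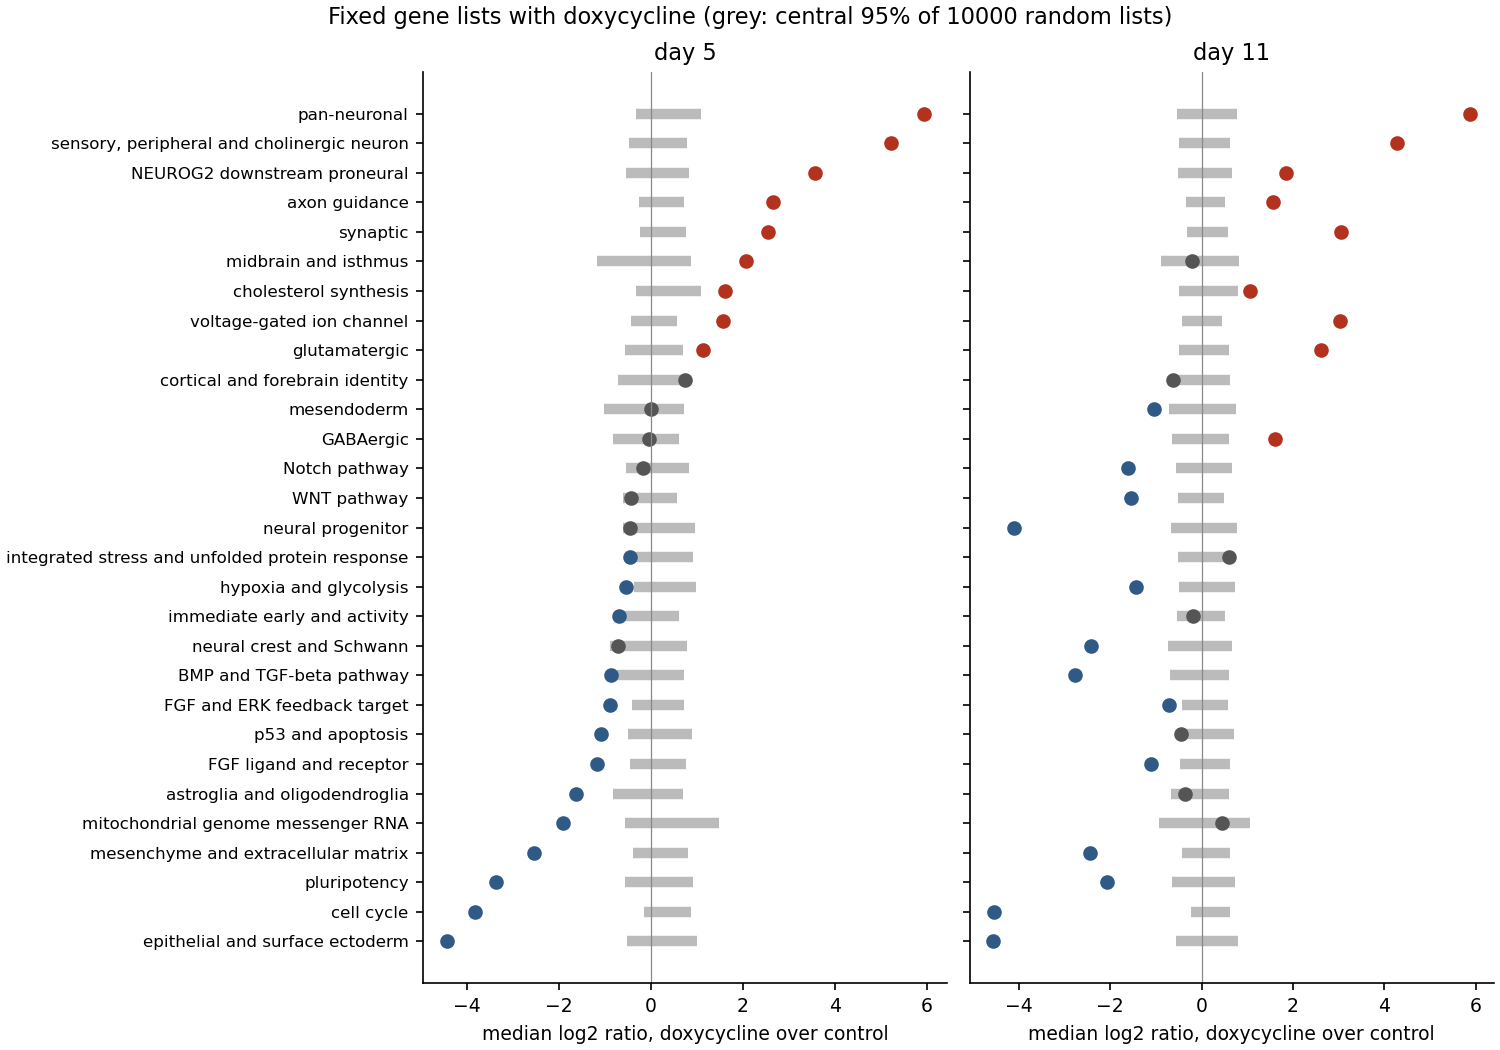
Median log2 ratio of each gene list, doxycycline over control, on day 5 and day 11. Points are list medians, red above and blue below the central 95% of 10000 random lists, which is drawn in grey. On each day 9 of 29 lists lay above that range and 13 below it.

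With doxycycline 3102 of 12895 genes were at least 4-fold different on day 5, 1625 higher and 1477 lower. On day 11 these were 2704 of 12655 genes, 1457 higher and 1247 lower. On both days 943 genes were higher, where 169 would be by independent overlap, and 756 were lower, where 86.2 would be. Another 17 genes were higher on 1 day and lower on the other. Whether more genes were higher or lower depended on scaling. With library totals in place of TMM the share of higher genes went from 52.4% to 47.4% on day 5 (1411 higher and 1565 lower) and from 53.9% to 42.5% on day 11 (1203 higher and 1625 lower). With the authors' deposited normalized values it was 47.9% and 42.6%. The median log2 ratio of all genes went from 0.23 to 0.06 on day 5 and from 0.16 to -0.18 on day 11.

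In the cultures without doxycycline time and medium changed together, with 1 library per day. On day 5, 125 genes were at least 4-fold different from day 0, 100 higher and 25 lower, and on day 11 there were 548, 253 higher and 295 lower. On either day 654 genes passed. On day 11 the forebrain regulator SIX3 was at 246 CPM, against 1 count on day 0, and FGF8, a signal of the midbrain border, was at 76.3 CPM against 0.177 CPM. POU5F1 went from 1000 CPM on day 0 to 654 on day 5 and 38.9 on day 11, while MKI67 was at 338, 392 and 326 CPM. Against day 0 the medians on day 11 were -2.31 for pluripotency, 1.58 for neural progenitor, 1.26 for cortical and forebrain, 2.00 for midbrain and isthmus and 0.76 for axon guidance genes. That of BMP and TGF-beta genes was 1.29. The day-11 doxycycline medians given above for these lists are therefore against a control that had itself moved. Their shifts between day 5 and day 11 need not lie in the cultures with doxycycline. Mitochondrial messenger RNA had a median of 1.22 on day 5 and -1.08 on day 11, so the median of -1.91 given above for doxycycline on day 5 is against a control that was itself higher than day 0. Hypoxia and glycolysis genes had a median of -0.75 on day 5. With library totals the share of higher genes on day 5 was 67.8% in place of 80%. On day 11 it was 52.3% in place of 46.2% (302 higher and 275 lower). The median of all genes went from -0.12 to -0.22 on day 5 and from -0.07 to 0.09 on day 11.

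Between day 6 and day 12 of the FGF2 set the controls were in 3N medium without doxycycline, so time and the end of induction changed together. NEUROG2 fell from 7626 ± 116 to 52.0 ± 3.76 CPM (log2 change -7.20, adjusted p = 1.2e-16, edgeR quasi-likelihood test, n = 2 per group). NEUROD1 fell from 300.3 ± 7.65 to 6.28 ± 0.287 CPM. FGFR1 rose from 47.1 ± 0.681 to 143 ± 7.38 CPM, and FGFR3 fell from 7.02 ± 1.07 to 0.166 ± 0.00604 CPM. FGFR2 fell with a log2 change of -1.72 and FGF2 rose with one of 1.01. In all 12895 of 20142 genes were called, 6395 higher and 6500 lower on day 12, and 6431 of them changed at least 2-fold.

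Genes of mature neuronal function rose. The membrane proteins CTXN3 and MDGA2 had no counts on day 6 and were at least 407-fold and at least 159-fold higher on day 12. The calcium sensor HPCAL4 rose from 3 counts (ratio 762, counting interval 260 to 3698). EOMES, of the NEUROG2 downstream proneural list and not a gene of mature function, also rose from 3 counts (ratio 1221, 418 to 5925). IRS4 and the matrix protein TNR rose with log2 changes of 9.01 and 8.96. Of 41 synaptic genes 33 rose and 8 fell (median 1.23, camera adjusted p = 5.2e-13, and adjusted p = 0.0659 with an estimated correlation). SHANK1 went from 1.40 ± 0.275 to 63.9 ± 4.27 CPM and NLGN3 from 2.43 ± 0.0887 to 80.6 ± 1.19 CPM. Of 43 voltage-gated ion channel genes 31 rose and 5 fell (adjusted p = 5.8e-11, and adjusted p = 0.190 with an estimated correlation), and SCN2A rose from 1.48 ± 0.214 to 108 ± 5.96 CPM. Of 12 GABAergic genes 9 rose, with the receptor subunits GABRA3, GABRA2 and GABRB2 among those that rose, and of 23 glutamatergic genes 17 rose and 5 fell. The GABAergic median was 3.44, or 3.24 with 1 gene at its bound. SLC17A7 was among the glutamatergic genes that fell, from 516 ± 0.270 to 51.1 ± 0.439 CPM. Of 44 axon guidance genes 27 rose and 9 fell, and of 25 pan-neuronal genes 15 rose and 8 fell. SLC5A7, the choline transporter, rose from 0.794 ± 0.0903 to 208 ± 23.6 CPM.

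Genes of dividing and early cells fell. OLIG3 and E2F2 had no counts on day 12 and were at least 517-fold and at least 179-fold lower. C2orf91, CHRNA1 and HEYL fell with log2 changes of -9.96, -9.86 and -9.20, and ACSF2 fell to 1 count, 720-fold lower (counting interval 129 to 28470). Of 38 cell cycle genes 37 fell (median -4.35, camera adjusted p = 3.1e-39, and adjusted p = 0.0659 with an estimated correlation), as did 16 of 22 NEUROG2 downstream proneural genes (median -2.96, adjusted p = 1.0e-22, and adjusted p = 0.0645 with an estimated correlation) and 14 of 20 Notch genes (median -3.01, adjusted p = 1.8e-09, and adjusted p = 0.0659 with an estimated correlation). NHLH1 fell from 2053 ± 18.6 to 15.9 ± 0.748 CPM and MFNG from 132 ± 4.17 to 0.287 ± 0.225 CPM. Of 26 FGF and ERK feedback targets 14 fell and 8 rose, and SPRY4, an inhibitor of FGF signalling, fell from 85.1 ± 6.07 to 7.52 ± 1.52 CPM. Of 13 mitochondrial messenger RNAs 11 fell. Among 5 HOX and caudal genes 2 rose and 2 fell, with GBX2 at 1.40 ± 0.578 and then 39.3 ± 0.957 CPM. Camera called 18 lists with the preset correlation and 0 with an estimated one, where the smallest adjusted p was 0.0645, and fry called 25. For the other lists given here the estimated-correlation adjusted p was 0.0659 for GABAergic genes, 0.190 for FGF and ERK targets, 0.276 for axon guidance, 0.288 for glutamatergic, 0.336 for pan-neuronal and 0.541 for mitochondrial genes.

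Early FGF2, given with doxycycline, left no detected change in single genes. NEUROG2 was at 7626 ± 116 CPM in controls and 7772 ± 83.1 CPM with FGF2. The transcription factor ETV4, a common readout of FGF signalling through ERK kinase, was at 3.18 ± 0.0639 and 3.14 ± 0.121 CPM. The ERK phosphatase DUSP6 was at 22.6 ± 1.04 and 20.1 ± 0.459 CPM, SPRY4 at 85.1 ± 6.07 and 68.4 ± 15.3 CPM, and EGR1, an immediate early gene, at 1.80 ± 0.363 and 1.87 ± 0.239 CPM. FGFR1 was at 47.1 ± 0.681 and 48.8 ± 4.36 CPM. edgeR called 0 of 20142 genes (smallest adjusted p = 0.927), with 658 genes at an unadjusted p under 0.05, where 1007 would be by chance. DESeq2 called 0 genes with 314 under 0.05, limma voom called 0 with 682, and the authors' deposited tables from DESeq2 and limma also hold 0. Without day-6 FGF2 replicate 1, edgeR made 2523 calls, 1172 higher and 1351 lower. The replicates of this group differed by a chi-square per degree of freedom of 21.2 against counting error alone, and those of the other 3 groups by 3.02 to 3.46.

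Camera called 4 lists with early FGF2 at the preset correlation. Ion channel genes were lower (median -0.09, adjusted p = 0.0150), as were cell cycle genes (-0.08, 0.0113) and axon guidance genes (-0.08, 0.0150), and stress response genes were higher (0.10, 0.0113). No member of these lists was called. With an estimated correlation the adjusted p was 0.810 for each of the 4, fry called 0 lists, and without day-6 FGF2 replicate 2 the adjusted p was 0.597 for ion channels, 0.762 for cell cycle, 0.653 for axon guidance and 0.726 for the stress response. The FGF and ERK feedback targets had a median of -0.05 and an adjusted p of 0.517.

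Late FGF2, given after doxycycline was withdrawn, raised targets of FGF and ERK signalling. ETV4 (ENSG00000175832, chromosome 17, 43527844 to 43579620) rose from 1.73 ± 0.819 to 98.2 ± 2.10 CPM, 56.1-fold (log2 change 5.81, edgeR quasi-likelihood test, adjusted p = 4.0e-11). SPRY4 (ENSG00000187678) rose from 7.52 ± 1.52 to 68.1 ± 0.0488 CPM, a log2 change of 3.17 (adjusted p = 9.6e-09). DUSP6 rose from 34.3 ± 2.84 to 238 ± 21.4 CPM, a log2 change of 2.79, and shares 40.5% of its exon bases with another gene. SPRY2 rose from 13.3 ± 0.0109 to 46.5 ± 0.256 CPM and EGR1 from 0.812 ± 0.0589 to 5.26 ± 0.0727 CPM. Of 26 FGF and ERK feedback targets 17 rose and 0 fell (19 rose adjusted over the list alone), with a median of 0.78 (camera adjusted p = 1.2e-113, and adjusted p = 0.00106 with an estimated correlation).

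**Figure D3:**
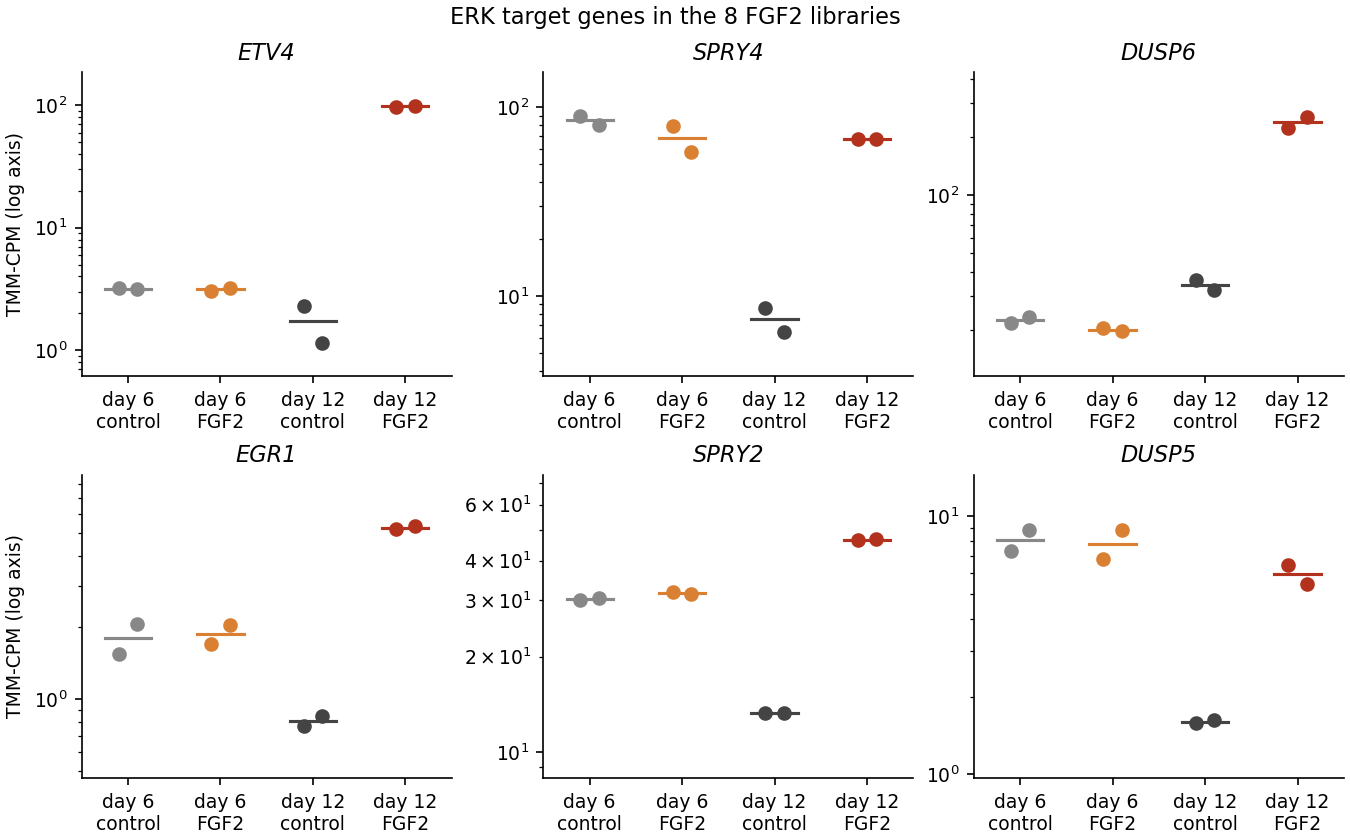
TMM-scaled CPM on a log axis of 6 target genes of ERK signalling in the 8 FGF2 libraries. Points are libraries and bars are means of 2. With late FGF2 each gene lay above its day-12 control in both libraries, and on day 6 no gene was called: ETV4 was at 3.18 and 3.14 CPM.

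Of the other genes among the 10 with the largest rise at a mean of at least 5 CPM, DCBLD1 rose from 3.97 ± 0.0618 to 37.7 ± 2.01 CPM, and the galanin receptor GALR1 from 6.21 ± 1.48 to 52.7 ± 0.451 CPM. KITLG, the ligand of the KIT receptor, rose from 47.4 ± 3.81 to 355 ± 25.6 CPM. RGS16, a regulator of G protein signalling, NWD2, the ubiquitin ligase subunit FBXW7 and the adaptor SHC4 rose with log2 changes of 2.31, 2.23, 2.08 and 2.01. The largest fall among genes at that level was that of CYP26A1, an enzyme that degrades retinoic acid, from 12.1 ± 1.47 to 1.80 ± 0.483 CPM (log2 change -2.73, adjusted p = 5.5e-06). It shares 25.2% of its exon bases with another gene. ANOS1, the Kallmann syndrome protein anosmin, fell from 181 ± 33.5 to 48.2 ± 5.98 CPM. PRLHR, a peptide receptor, fell from 279 ± 37.7 to 133 ± 16.6 CPM, and PHOX2A from 10.2 ± 0.572 to 4.71 ± 0.419 CPM. TMEM132C, the purine receptor P2RY1, DGKK, PDZRN3, SHROOM3 and CHST9 fell with log2 changes from -1.36 to -1.03. Of these, CHST9 lost its call without day-12 control replicate 1 (adjusted p = 0.248), day-12 control replicate 2 (0.171) or day-12 FGF2 replicate 2 (0.449). DGKK lost it without either replicate 2 of day 12 (0.0544 and 0.0660), and SHROOM3 without day-12 control replicate 2 (0.0709).

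Neuronal genes changed in both directions. RET, the receptor of GDNF, rose from 264 ± 8.29 to 489 ± 11.4 CPM, and the sensory neuron factor DRGX and the peptide SST rose with log2 changes of 1.00 and 1.03. Among 28 sensory, peripheral and cholinergic genes 6 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.00361, and adjusted p = 0.189 with an estimated correlation). Of 41 synaptic genes 4 rose and 0 fell, among them NRXN3 from 13.1 ± 0.388 to 37.8 ± 3.07 CPM and RIMS1 from 83.2 ± 3.63 to 127 ± 3.58 CPM. Of 25 pan-neuronal genes 4 rose and 0 fell. The neurofilament NEFM rose from 4115 ± 39.3 to 6051 ± 146 CPM. Camera did not call these lists (adjusted p = 0.161 and 0.0909). Of 44 axon guidance genes 9 rose and 4 fell (10 and 10 adjusted over the list alone), with a median of -0.05 and a mean of 0.04. NRP1, a semaphorin receptor, rose from 118 ± 3.25 to 237 ± 1.84 CPM and SEMA3C fell from 497 ± 25.5 to 301 ± 24.4 CPM. Of 43 ion channel genes 2 rose and 2 fell, and the list as a whole was lower (median -0.09, adjusted p = 0.0306, and adjusted p = 0.644 with an estimated correlation). This call was also lost after trends with gene length and GC content were removed (median -0.10, adjusted p = 0.174), and the synaptic list was then called (adjusted p = 0.0417). The progenitor factor SOX2 fell from 66.5 ± 1.26 to 45.1 ± 1.62 CPM. Without 1 of the 4 libraries of day 12 at a time (control replicates 1 and 2, then FGF2 replicates 1 and 2), 2, 2, 2 and 2 pan-neuronal genes rose, and 4, 3, 3 and 4 sensory, 7, 3, 4 and 7 axon guidance and 2, 1, 1 and 1 ion channel genes. In each case 1 axon guidance gene and 0 ion channel genes fell. Without either day-6 control library 1 ion channel gene rose. Without either day-6 FGF2 library 6 pan-neuronal genes rose and 4 fell, 6 synaptic genes rose and 2 fell, 2 sensory and 9 axon guidance genes fell, and 3 ion channel genes rose and 6 fell. NEUROG2 was at 52.0 ± 3.76 and 51.2 ± 2.69 CPM and FGFR1 at 143 ± 7.38 and 151 ± 2.80 CPM.

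Further lists called with late FGF2 were immediate early genes, hypoxia and glycolysis, cholesterol synthesis, the stress response, mitochondrial messenger RNA, and astroglia and oligodendroglia, all higher. Of 19 immediate early genes 8 rose and 1 fell (11 and 4 adjusted over the list alone; median 0.35, adjusted p = 4.4e-07, and adjusted p = 0.0601 with an estimated correlation). VGF, a secreted neuropeptide precursor, rose from 97.3 ± 0.793 to 198 ± 11.8 CPM and JUNB rose with a log2 change of 0.99. Of 23 cholesterol genes 1 rose among all genes, STARD4, and 17 rose adjusted over the list alone (median 0.23, adjusted p = 3.0e-09, and adjusted p = 0.249 with an estimated correlation). Of 22 hypoxia and glycolysis genes 3 rose and 1 fell (11 and 2 adjusted over the list alone; adjusted p = 3.6e-06, and adjusted p = 0.533 with an estimated correlation). Of 25 stress response genes 3 rose (4 adjusted over the list alone; adjusted p = 0.00302, and adjusted p = 0.533 with an estimated correlation). Of 12 glial genes 2 rose (3 rose and 1 fell adjusted over the list alone; adjusted p = 0.0410, and adjusted p = 0.459 with an estimated correlation, 0.158 with fry and 0.0567 with the sample number as a block), and SOX8 rose with a log2 change of 1.15. None of 13 mitochondrial messenger RNAs was called (median 0.12, adjusted p = 0.0201, and adjusted p = 0.618 with an estimated correlation). After trends with gene length and GC content were removed the call of that list was lost (median 0.06, adjusted p = 0.124). Fry called 4 of the 30 lists. Without 1 of the 4 libraries of day 12 at a time (control replicates 1 and 2, then FGF2 replicates 1 and 2), 3, 5, 3 and 3 immediate early genes rose. For hypoxia and glycolysis these counts were 6, 0, 1 and 3, for the stress response 1, 0, 2 and 0, and for glial genes 3, 1, 2 and 1. Of these 4 fits the hypoxia gene that fell kept its call only without FGF2 replicate 2, and the immediate early gene that fell lost its call without that library. Without either day-6 FGF2 library 18 cholesterol, 11 hypoxia, 6 stress response, 5 mitochondrial and 3 glial genes rose, and 2 hypoxia, 2 immediate early and 1 glial genes fell.

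In all, late FGF2 changed 437 of 20142 genes (2.17%), 329 higher and 108 lower, and all moved the same way in both numbered pairs. From day 6 to day 12, 12894 of 12895 called genes did so too, so this follows largely from being called and is no separate support. Of the 437 genes, 144 changed at least 2-fold, 119 higher and 25 lower. The balance depended on the libraries fitted. In a fit of only the 4 day-12 libraries 812 genes were higher and 526 lower (60.7% higher, against 75.3% of the 437). The authors' deposited DESeq2 table holds 834 genes at an adjusted p under 0.05, 498 higher and 336 lower, and the authors' deposited limma table holds 1306, 739 higher and 567 lower. Of the 414 genes called here that are in those tables, 340 are called in the authors' deposited DESeq2 table and 412 in the authors' deposited limma table, each with the same sign. The count depended on single libraries. It was 1171 without day-6 FGF2 replicate 1 and 1188 without replicate 2 of that group. It was 217 and 184 without day-12 control replicates 1 and 2, and 219 and 194 without day-12 FGF2 replicates 1 and 2.

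Whether late and early FGF2 acted differently was tested as the difference between both effects. It was called for 147 genes, 130 with a larger rise, or smaller fall, late and 17 the other way, and 78 of them differed at least 2-fold. ETV4 (difference of log2 changes 5.83, adjusted p = 2.8e-08), HAPLN1 (3.50), SPRY4 (3.49), DCBLD1 (3.34), GALR1 (3.16) and KITLG (3.12) led the former among genes with a mean of at least 5 CPM. HAPLN1, a matrix link protein, was at 15.4 ± 1.84 and 14.3 ± 1.31 CPM on day 6 and went from 0.543 ± 0.137 to 5.73 ± 0.317 CPM on day 12. Of 26 FGF and ERK feedback targets 13 were called (18 adjusted over the list alone), all with the larger effect late (median 0.92, camera adjusted p = 1.3e-98, and adjusted p = 0.00131 with an estimated correlation). RET, VGF, NRP1 and SOX8 also had the larger rise late, with differences of 0.90, 0.93, 1.16 and 1.39. ANOS1 (-1.82) led the genes of that level with the larger fall late. The count was 81 and 86 without day-6 control replicates 1 and 2, 1345 and 353 without day-6 FGF2 replicates 1 and 2, 97 and 78 without day-12 control replicates 1 and 2, and 91 without day-12 FGF2 replicate 2.

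**Figure D4:**
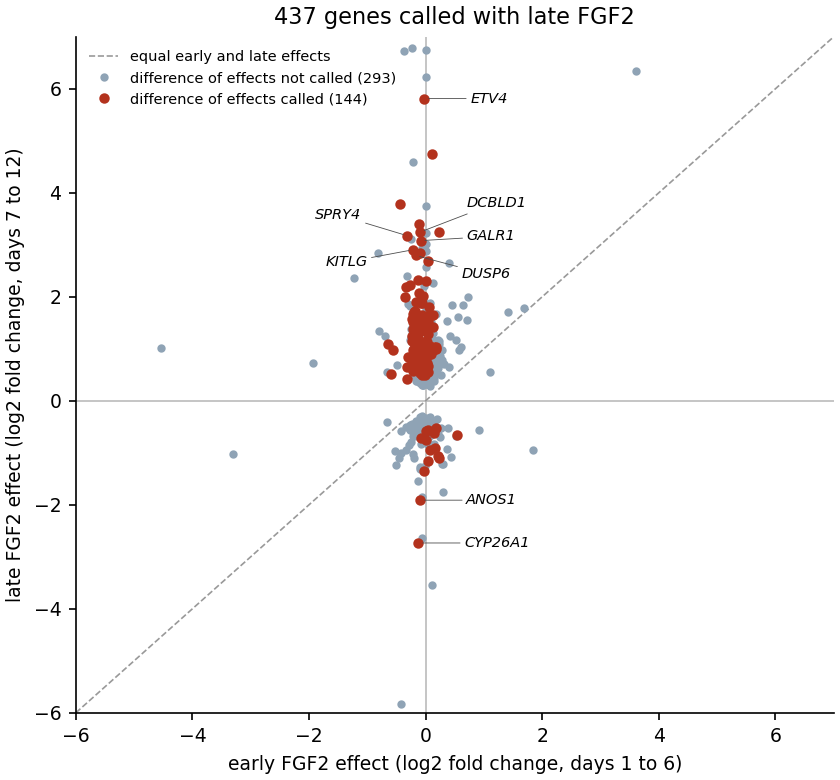
Log2 change with early FGF2 (x axis) and late FGF2 (y axis) for the 437 genes called with late FGF2. Red points are the 144 genes whose difference was also called, and grey points are the other 293.

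The genes that doxycycline changed on both days gave sets from other libraries for the FGF2 comparisons. From day 6 to day 12, 646 of 942 genes of the higher set rose and 190 fell (median 0.79, camera adjusted p = 5.0e-18). Of 661 genes of the lower set 54 rose and 500 fell (median -1.90, adjusted p = 9.2e-26). Both had an adjusted p = 0.0647 with an estimated correlation. With late FGF2 neither set was called (adjusted p = 0.464 and 0.261). With early FGF2 the lower set was lower still (median -0.07, adjusted p = 0.000601, and adjusted p = 0.552 with an estimated correlation). For the difference of effects it was higher (adjusted p = 0.00768, and adjusted p = 0.609 with an estimated correlation), and this call was also lost with the set defined at 8-fold (adjusted p = 0.0929).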

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

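Of the tests in this part, the length and GC test of the library that stands apart, and the test of the lists without that library, had their predictions written before the outcome was measured. Both were added after the data were seen, and the other tests were chosen after the result was seen.

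The effect of late FGF2 differed from that of early FGF2 by a test of the difference itself in 147 genes. The differences of log2 changes were 5.83 for ETV4, 3.50 for HAPLN1, 3.49 for SPRY4, 3.34 for DCBLD1, 3.16 for GALR1 and 3.12 for KITLG. In the other direction they were -1.82 for ANOS1, -1.50 for CSPG5, -1.34 for PHOX2A, -1.33 for TMEM132C, -1.27 for PRLHR and -1.20 for CACNA2D3. The calls of CSPG5, PHOX2A, PRLHR and CACNA2D3 were lost without day-6 control replicate 1 (adjusted p = 0.150, 0.0840, 0.0760 and 0.0874). With limma voom the calls of CSPG5 (0.140) and PRLHR (0.0560) were lost. Those of CSPG5 and TMEM132C were lost without day-6 control replicate 2 (0.137 and 0.0851), and that of PHOX2A without replicate 1 of either day-12 group (0.0661 for the control and 0.0735 for FGF2). CSPG5, TMEM132C and CACNA2D3 lost theirs without day-12 control replicate 2 (0.0644, 0.0755 and 0.0573), and CSPG5 and TMEM132C without day-12 FGF2 replicate 2 (0.0516 and 0.0901).

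Lists whose effect differed had a camera adjusted p of 1.3e-98 for FGF and ERK feedback targets, 2.6e-06 for cholesterol synthesis, 0.00288 for hypoxia and glycolysis and 0.00507 for immediate early genes. It was 0.0164 for glial, 0.0351 for pluripotency and 0.0437 for axon guidance genes. With an estimated correlation the adjusted p was 0.00131 for FGF and ERK feedback targets and 0.314 to 0.767 for the other 6.

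The ERK targets rose with late and not with early FGF2. Labels exchanged between treated and untreated libraries of day 6 are argued against: over the 7 ways to set 1 or 2 of the 4 day-6 libraries against the others, the largest absolute median log2 difference of the 17 targets that rose late was 0.0723, while wrong labels that hide the same treatment of all 4 would also give a value near 0 and stay open. For spread on day 6, the early interval lay wholly below the late one for 16 of 17 targets. The 17 were chosen by their late rise, and the intervals use a spread estimated over all 4 groups. Replicates of day-6 FGF2 differed most (chi-square per degree of freedom of 21.2), so these intervals may be too narrow. Spread is argued against only under that shared estimate. Named after their values were seen, SPSB1, SPRED1, SPRED3 and IL17RD had no call of the difference itself (edgeR adjusted p = 0.486, 0.141, 0.0732 and 0.0570), and the other targets had one. Targets already near their late level on day 6 without added FGF2 are argued against for 12 of 17, which were under 80% of that level. They stay open for the other 5, SPSB1, SPRY4, ETV1, DUSP5 and CCND1 (named after their values were seen). The late level was no ceiling on day 6, since SPSB1 was at 605% of it in day-6 controls. Whether the 12 could have risen further on day 6 therefore stays open. The groups differ in day, in doxycycline, in medium and in the levels of NEUROG2 and FGF receptors together. Early FGF2 covered the 2 days in E8 medium, and late FGF2 was given in 3N medium only. Which of these could account for the difference was not tested and stays open.

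Day-6 FGF2 replicate 2 stood apart from the other day-6 libraries. Its log2 difference from them fell with exon length (rho -0.560) and rose with GC content (rho 0.375). A response of the 17 targets to FGF2 in that library alone is argued against by their median log2 difference from the controls, -0.0900. A response through other genes was not tested. With trends removed, the library's difference from day-6 FGF2 replicate 1 had a rho of -0.0507 with the change from day 6 to day 12. This argues against a shift along that change, which joins time with the end of doxycycline and from which the trends were not removed. A culture at another stage under doxycycline need not shift along it and stays open. A trend with length and GC may account for part of it: with that library alone for early FGF2 there were 2523 calls before and 871 after the trends were removed, 549 of them in both. What else sets the library apart stays open.

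With early FGF2, 4 lists were called. A library that stands apart is a candidate explanation, since 0 of the 4 were called in the same direction without day-6 FGF2 replicate 2. For the ion channel, axon guidance and stress response lists its trend with length and GC is a candidate cause, since 0 of these 3 were called after the trends were removed, when their medians had gone from -0.09, -0.08 and 0.10 to -0.06 (quartiles -0.12 and 0.03), -0.02 (-0.08 and 0.04) and 0.07 (0.01 and 0.13), so part of each shift was left. For the cell cycle list that trend is argued against as the whole cause, since its adjusted p was then 3.1e-05. A biological effect of early FGF2 on these lists was not shown.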

How the results depend on the processing

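The length and GC correction, the early lists without day-6 FGF2 replicate 2 and the authors' normalized values were tests chosen after the data were seen. No call of a named gene, list or set reversed. The balance of higher and lower genes did: with library totals it went from 1625 and 1477 to 1411 and 1565 for doxycycline on day 5, from 1457 and 1247 to 1203 and 1625 on day 11, and from 253 and 295 to 302 and 275 for the day-11 control, and the cause was not tested. For 135 named genes of the doxycycline set the ratio moved beyond its counting interval in 342 of 540 alternatives on day 5 and 327 of 540 on day 11, and none reversed. Named genes of the FGF2 set include some without a call, which keep their status by staying uncalled. From day 6 to day 12, 136 genes, 135 of them called, kept their status under all 2169 alternatives. With late FGF2 71 genes, 64 of them called, kept theirs in 1039 of 1130, and calls were lost in 91 (25 genes). For the difference 34 genes, 27 of them called, kept theirs in 459 of 508, and calls were lost in 49 (13 genes). Calls with late FGF2 and for the difference stayed within 1.5 times under DESeq2 (438 and 188), limma voom (472 and 132), RLE (427 and 146), library totals (413 and 144), the number as a block (598 and 206) and the stricter filter (347 and 128). Deviations of libraries of the same number correlated at 0.004 to 0.098 between groups, and the main model does not pair them.

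Leaving out 1 library gave 0 to 2523 calls for early FGF2, 184 to 1188 for late FGF2 and 78 to 1345 for the difference. Early FGF2 moved without day-6 FGF2 replicate 1. Late FGF2 moved without any library of day-6 FGF2 or day 12, and the difference without any library but day-12 FGF2 replicate 1. The common dispersion was 0.00558 with all 8 libraries and 0.00210 without either day-6 FGF2 library. This goes with the higher counts for late FGF2 and the difference. Early FGF2 moved only without replicate 1 of that group, although the dispersion was as low without replicate 2. A lone library is assumed to vary like the other groups.

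Without the filter late FGF2 had 656 calls and the difference 268, with only the 4 libraries compared late FGF2 had 1338, and after length and GC correction the difference had 221 and late FGF2 637, 433 of the 437 among them: the cause was not tested. Of these 637, 427 were higher and 210 lower (67.0% higher, against 75.3% of the 437, 329 higher and 108 lower). A 2-fold minimum, a stricter threshold, left 144, 78 and, for day 12 against day 6, 6431. A 2-fold in place of a 4-fold threshold, which is looser, gave 6467 and 5796 genes for doxycycline on days 5 and 11 and 1186, 1701 and 2653 for controls on day 5, day 11 and either day. A pseudocount of 5 CPM, which shrinks ratios of low genes, left 52, 307 and 351.

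Lists called with an estimated correlation were 0 early, 1 late, 1 for the difference and 0 for day 12 against day 6. With fry they were 0 early, 4 late and 2 for the difference. After length and GC correction they were 1 early, 9 late (7 of the main 9), 10 for the difference (all 7 among them) and 16 for day 12 against day 6 (16 of 18). Early lists were 2, none of the main 4, without day-6 FGF2 replicate 2. Of the doxycycline sets 0 were called with an estimated correlation and 2 with fry. The cause was not tested. Depth limits genes with few counts, whose ratios carry wide intervals.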

Other observations

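The tests of retinoid genes and of the numbered cultures were chosen after the result was seen. The genes in the next paragraph were chosen after their values were seen.

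PAX5, a midbrain factor, was at 46.9 CPM on day 6 and rose with late FGF2 from 4.66 to 15.5 CPM (edgeR adjusted p = 8.0e-05). HRK, a promoter of apoptosis, was at 2.92 CPM on day 6 and fell with late FGF2 from 89.8 to 47.7 CPM. ID4, an inhibitor of basic helix-loop-helix factors, rose from 158 to 261 CPM.

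Whether late FGF2 delays or speeds the change with time was tested across 20142 genes, with the late effect of 1 numbered pair against the time change of the other number. The rho was -0.127 and -0.155, between the bounds set beforehand, so a delay that may underlie the genes above cannot be told apart from none. Small correlations of this kind decide neither way.

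CYP26A1, which degrades retinoic acid, had the largest fall with late FGF2 among genes with a mean of at least 5 CPM. Lower retinoid signalling is a candidate explanation that the other retinoid response genes argue against: for 6 of 8 the interval excluded a fall of 0.5 on the log2 scale, with a median of 0.13.

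The titles name the libraries numbered 1 and 2 here hES-N2G1 and hES-N2G2, and those of the doxycycline set hES-N1, while the source names give hES-N1 for all 13. Whether these are cultures, clones or lines is not stated, so the 2 libraries of a group may be of either kind of replicate. Between numbers 1 and 2, 12 genes differed over all 8 libraries, 7 higher and 5 lower in number 2, 3 of them protocadherins. ZNF558 was at 22.7 and 41.4 CPM and PCDHA10 at 7.03 and 16.3 CPM. The numbers may mark separate cultures kept through both days. When the same 8 libraries were split by day, 13 genes were called both on day 6 alone and on day 12 alone. By chance 1.48 would be in any direction, and 11 of the 13 had the same direction. Since these libraries also gave the 12 genes, the overlap is not separate support for them. Against cultures kept through both days, of 167 genes called on day 6 and tested on day 12 only 38 (22.8%) had the same direction in both day-12 arms, no more than the 25% of random signs, so most day-6 calls did not carry over to day 12.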
